A study of Danio rerio with 10 samples.

How the data were processed

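Trunks of zebrafish embryos at 3 days post fertilization were dissociated with TrypLE, and single cells were sorted into 384-well plates and sequenced with the SORT-seq protocol. The 5 groups have 2 plates each. The deposited matrices hold expected counts, that is, estimated transcripts per gene and well. Per the submitters' processing notes the genome build was Zv9; the aligner, the counting tool and the annotation are not given in the sources used here. Checked on the values, 99.87% to 99.91% of them matched, to 3 significant digits, the correction of a whole UMI number for collisions among 4096 possible UMIs of 6 bases. A separate list of well barcodes did not match the wells of any plate and was not used here.

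Plates within a group are not stated to come from separate pools of embryos, so every p-value measures the spread between plates only. The titles of the metaphocyte plates also carry the wild-type tag, while their genotype and description give the mutant, which was used. Wells with at least 1000 UMIs were kept. Spike-ins and mitochondrially encoded genes were left out of library sizes, and the rows for GFP and mCherry were left out of the tests. The depth per kept well, a median of 3847 to 5756 UMIs, limits single-well detection, so genes were compared on sums over the wells of a plate.

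Wells were clustered with scanpy 1.11.5 and python-igraph 0.11.9 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3), on 2000 highly variable genes, 30 principal components, 15 neighbours and Leiden resolution 1. A cluster took a class name from marker lists when at least 3 markers, and at least 30% of a list, were raised by at least 2-fold and found in at least 20% of its wells. The rule that leaves clusters led by another tissue's genes unnamed was set after the clusters were seen. The class names rest on these lists, so list members are not independent evidence of a class.

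Sums per plate were rounded and compared with edgeR 4.0.16 (R 4.3.3, limma 3.58.1), with TMM normalization, filterByExpr, a term per group, and the quasi-likelihood F test over all 10 plates, which left 5 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes come from this fit and carry its SE, and the CPM given with them are TMM-scaled means of 2 plates with their SD. The CPM of the receptor genes and reporters over all kept wells are not TMM-scaled. The 7 comparisons of all wells, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. The 5 comparisons within a class were chosen after. They use the same fit on macrophage-like (3 residual degrees of freedom), neutrophil-like (4) or blood progenitor-like wells (2).

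Named genes were csf1ra, csf1rb, fli1a, mpeg1.1, mpeg1.2 and mpx in every comparison. To these were added the 10 genes with the largest log2 fold change in each direction (5 for the interaction) among called genes with a symbol, at least 50 CPM in the higher group and no overlap between the groups' plates, ribosomal protein genes excepted. Up to 4 called members of each gene list could also be named. Non-overlap of 2 plates against 2 happens by chance in 2 of 6 assignments. The 35 lists, 16 of functions and 19 of cell types, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Of the members, 19 had no row in the files. Of 27865 features, 25097 had an identifier in the gene name table.

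Tested on simulated data in the comparison of mutant with wild-type bMs over all wells, edgeR recovered 2 of 98 genes changed by a log2 fold of 1 (2%) and 31.3% of those changed by 2, with 5.7% of its calls false. DESeq2 1.42.0 recovered 7.1% and 56.6%, with 16% false. In macrophage-like wells edgeR recovered 31.9% and 80.6% with 2.7% false, and in neutrophil-like wells 39.4% and 77.7% with 5.9% false. Each fit was simulated once. All plates shared the same mean profile apart from the changed genes, and the same spread per gene, as the fit assumes. The false shares need not hold for the real plates, whose gates and spreads differ.

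The alternatives were DESeq2's Wald test, DESeq2 size factors in edgeR, no filter on low counts beyond 1 count, plate number as a block, only the plates compared, and leaving out each plate. Others were wells with any UMI or at least 3000 UMIs, every well thinned to 1000 UMIs, leaving out wells of clusters named for other cell types, and cluster resolutions of 0.5 and 2. Leaving out wells of clusters named for other cell types kept the macrophage-like, neutrophil-like and unnamed wells only. Added after the data were seen were whole UMI numbers before the collision correction, values above 20 set to 20, only the larger macrophage-like cluster, and wells with at least 3 UMIs of mpeg1.1 in place of the class.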

Results

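The data are single-cell transcriptomes from the trunk of zebrafish embryos at 3 days post fertilization, made with SORT-seq, in which single cells are sorted into the wells of 384-well plates. The series title names the subject as macrophages that live in blood vessels, called bMs in the labels. The labels give 5 sorted groups of 2 plates each. Wild-type bMs carried GFP driven by mpeg and Cherry driven by fli1a. Wild-type macrophages carried GFP without Cherry, and wild-type neutrophils carried GFP driven by mpx. The other 2 groups came from embryos mutant for both csf1ra and csf1rb, the paired copies of the colony stimulating factor 1 receptor gene. They are double-positive cells, again called bMs, and GFP-positive Cherry-negative cells, called metaphocytes, which are epidermal cells that resemble macrophages.

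Between 249 and 366 wells per plate reached 1000 UMIs (unique molecular identifiers, which count molecules) and were kept. Their total per plate lay between 1248730 UMIs (wild-type macrophage plate 1) and 2337854 UMIs (wild-type bM plate 2), and the median well held 3847 to 5756 UMIs. The wild-type macrophage gate lost most wells to the minimum, 108 in plate 1 and 90 in plate 2.

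The mutated genes were still transcribed in the mutant plates. In all kept wells, csf1ra reached 50.2 ± 0.60 UMIs per 1000000 UMIs of the plate's kept wells (CPM; SD, n = 2) in mutant bMs and 25.4 ± 2.8 CPM in wild-type bMs. csf1rb reached 37.1 ± 0.10 CPM in mutant bMs and 39.0 ± 1.1 CPM in wild-type bMs. The labels do not describe the alleles, and SORT-seq reads the 3′ end of a transcript, which can lie outside a lesion, so these levels check neither genotype. In the metaphocyte plates csf1ra stood at 63.9 CPM in plate 1 and 422 CPM in plate 2. csf1ra was found in 24.9% of plate 1's wells (95% exact binomial interval 19.7 to 30.7) and in 70.3% of plate 2's wells (65.3 to 75.0). Intervals and floors for single plates cover counting error only.

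GFP transcripts were most abundant in the neutrophil gate, at 2505 ± 93.9 CPM. They stood at 256 ± 40.1 CPM in wild-type bMs, 261 ± 34.1 CPM in macrophages, 146 ± 40.2 CPM in mutant bMs and 61 ± 31.2 CPM in metaphocytes (SD, n = 2 each). mCherry transcripts were found in 1.7% and 4.8% of wild-type bM wells and in 6.6% and 14.8% of mutant bM wells. They were found in at most 1.2% of the wells of any plate sorted without Cherry. fli1a, whose promoter drives Cherry, reached 162 ± 3.5 CPM in wild-type bMs and 140 ± 19.4 CPM in mutant bMs. It reached 27.8 ± 10 CPM in macrophages, 39.8 ± 4.9 CPM in neutrophils and 6.4 ± 2.5 CPM in metaphocytes. mpeg1.1 reached 489 ± 63.7 CPM in wild-type bMs, 350 ± 39.9 CPM in macrophages and 37.1 ± 11.5 CPM in metaphocytes.

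**Figure D1:**
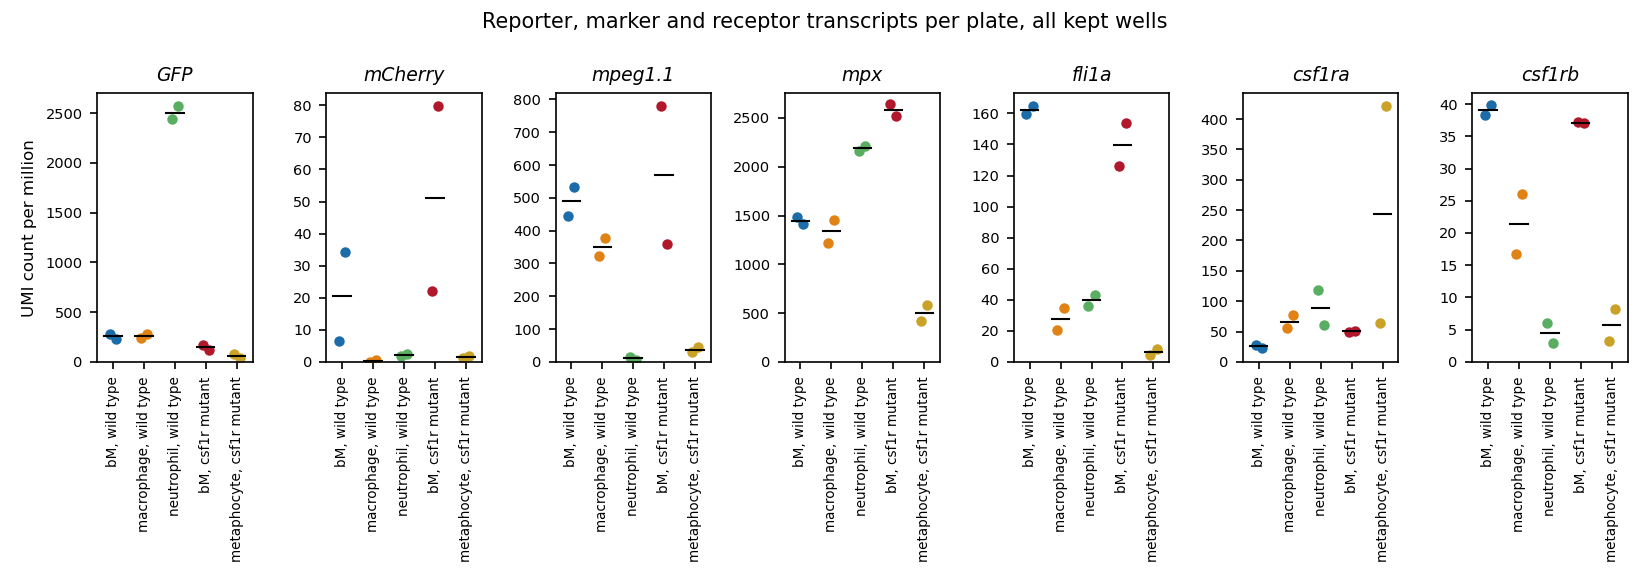
UMI counts in CPM of the GFP and mCherry reporters, mpeg1.1, mpx, fli1a, csf1ra and csf1rb in all kept wells. Each point is a plate and each line the mean of a group's 2 plates; csf1ra in the metaphocyte plates stands at 63.9 and 422 CPM.

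Clustering of all kept wells gave 24 clusters, and marker lists gave most of them a class name. No gate was one class. In the wild-type bM gate, macrophage-like wells made up 34.3% ± 2.96 (SD, n = 2) of the kept wells. Blood progenitor-like wells made up 19.4% ± 3.63, neutrophil-like wells 16.6% ± 1.09 and erythroid-like wells 11.98% ± 2.3. In the wild-type macrophage gate, 37.0% ± 0.08 were neural crest and pigment-like (pigment-like from here on), 23.8% ± 2.06 macrophage-like and 13.6% ± 1.57 neutrophil-like. In the neutrophil gate, 45.5% ± 2.76 were pigment-like and 36.3% ± 1.1 neutrophil-like. In the mutant bM gate, 41.1% ± 12.9 were macrophage-like, 26.6% ± 1.77 neutrophil-like, 13.3% ± 7.04 blood progenitor-like and 4.36% ± 1.94 erythroid-like. In the metaphocyte gate, 72.5% ± 8.98 were pigment-like, 9.38% ± 8.21 muscle-like and 3.14% ± 0.60 macrophage-like. Of the 287 pigment-like wells of metaphocyte plate 2, 213 lay in cluster 19, whose 10 leading genes held 0 markers of the pigment list and 1 of another class, so its name is uncertain. Among the pigment-like clusters, tyrp1a and dct led cluster 18 (21 wells), pax7b cluster 19 and pah cluster 17 (398 wells). Cluster 17 held 124 and 123 wells of the neutrophil gate. Its 10 leading genes also held 0 markers of the pigment list, while 6 of the list's 12 markers were raised in it. Endothelial-like wells were 0.56% of wild-type bM wells and 1.38% ± 1.53 of mutant bM wells, although Cherry marks vessels.

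Clusters 7 and 8, which carried cartilage genes, and clusters 10 (cell cycle genes) and 13 (kidney tubule genes) stayed unnamed. They held 15.1% ± 3.25 of wild-type bM wells, 10.5% ± 1.77 of mutant bM wells, 6.66% ± 2.04 of macrophage wells, 8.67% ± 0.40 of neutrophil wells and 6.57% ± 1.58 of metaphocyte wells. Cluster 8 met the marker rule for neutrophils (15 of 17 markers) and cluster 13 that for metaphocytes (8 of 12). Only the rule set after the clusters were seen left these 2 unnamed. No cluster was named metaphocyte, and cluster 13 held 1 and 0 wells of metaphocyte plates 1 and 2. The metaphocyte marker grn2 stood at 0.4 CPM in the metaphocyte gate and 8.9 CPM in the macrophage gate. The class shares depended on the cluster resolution. At resolution 0.5 the blood progenitor-like share was 35.14% in wild-type and 21.5% in mutant bMs, the macrophage-like share of wild-type bMs was 45.5%, and no cluster was named erythroid. At resolution 2 the macrophage-like share of wild-type bMs was 40.7%. A share of 2 plates against 2 allows 6 assignments, so no permutation test can reach 0.05 and none was run. The neutrophil-like share of the bM gate was larger in both mutant plates than in both wild-type plates. The erythroid-like and unnamed shares were smaller in both mutant plates. For the unnamed share this direction turned around under every alternative. It was 2.79% in wild-type and 4.35% in mutant bMs at resolution 0.5, and 9.48% and 10.41% at resolution 2. With at least 3000 UMIs per well it was 2.27% and 4.01%. The macrophage-like share differed by less than the spread between the mutant plates.

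**Figure D2:**
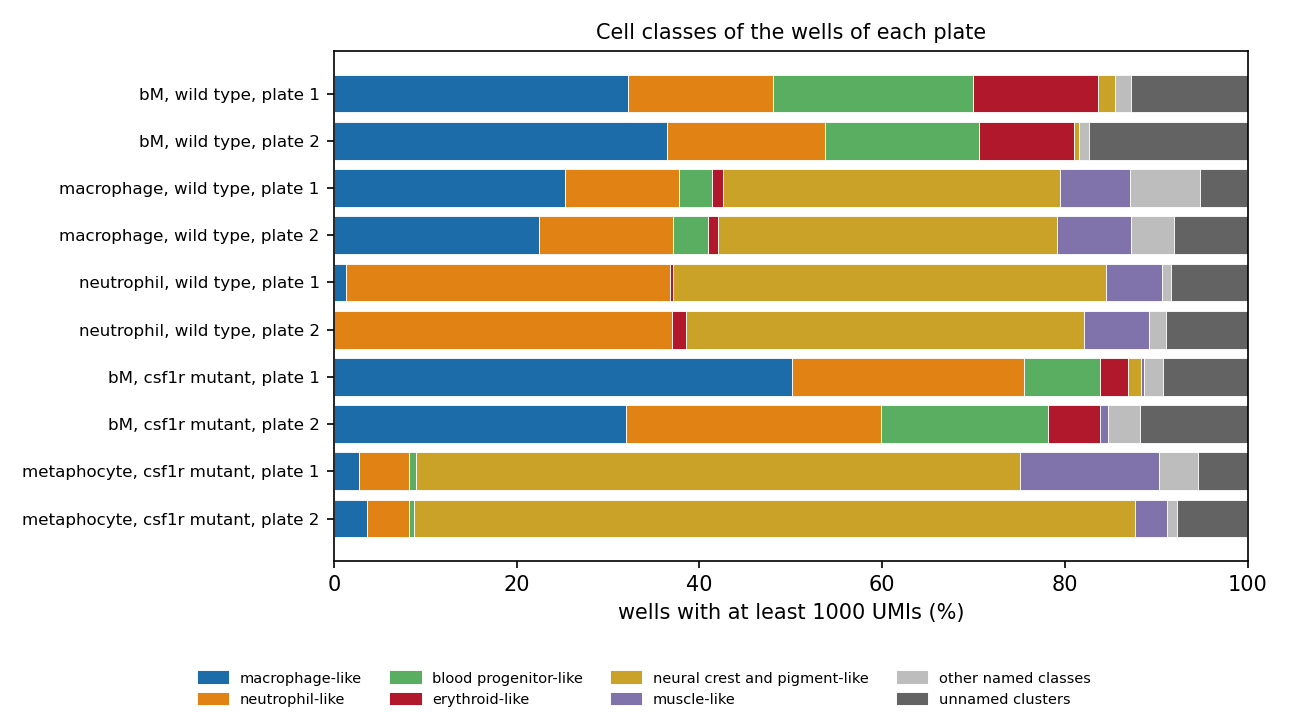
Share of kept wells per class in each of the 10 plates, in percent. Bars are single plates; pigment-like wells make up 37.0% of the macrophage gate and 45.5% of the neutrophil gate on average.

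Comparing mutant with wild-type bMs asks what differs in these cells between the genotypes. Over all kept wells, edgeR called 25 of 12008 genes, 14 higher and 11 lower in the mutant. It called 0 without wild-type bM plate 1, wild-type bM plate 2 or mutant bM plate 1, with 840, 720 and 921 genes at an unadjusted p under 0.05, and 15 without mutant bM plate 2. DESeq2 called 121 on all plates, 88 higher and 33 lower. Without the wells of clusters named for other cell types edgeR called 191, 129 higher and 62 lower. With at least 3000 UMIs per well it called 6, 2 higher and 4 lower. Of the 6 genes named first in every comparison, none passed: csf1ra had a log2 fold change of 1.02 (SE 0.76, adjusted p 0.628), csf1rb −0.03, fli1a −0.17, mpeg1.1 0.27, mpeg1.2 0.32 and mpx 0.88 (SE 0.22, adjusted p 0.164). Direction was not stable for csf1rb, fli1a and mpeg1.1, which changed sign under at least 1 alternative. The 3 genes higher under the naming rule were pacsin3 (2.63), nupr1b (2.11) and lect2l (1.67). The 5 lower were col9a3 (−3.19), moxd1 (−2.13), cmn (−2.07), aif1l (−2.02) and etv4 (−1.78). cmn is among the leading genes of the unnamed cartilage cluster 7, and col9a3 encodes a cartilage collagen. Cluster 7 held 14 and 14 wild-type and 17 and 6 mutant bM wells. Another cartilage gene, col2a1a, was found in 41.1% and 41.7% of wild-type and in 13.4% and 14.5% of mutant bM wells. Its level was 291.5 ± 26.6 CPM in wild-type and 261.5 ± 52.1 CPM in mutant bMs. Whether RNA from other wells lay behind this spread was not tested. The preset-correlation gene list test (camera) passed 15 of 34 lists. The neutrophil list had a median log2 fold change of 1.03, with 1 of 16 members called higher and 13 adjusted over the list alone. The cell cycle list had a median of −0.61, with 1 of 30 members called lower and 1 adjusted over the list alone. The shares of wells differed too: cluster 10, led by cell cycle genes, held 25 and 38 wild-type and 5 and 15 mutant bM wells. With an estimated correlation no list passed in any comparison of all wells or of a class.

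Because the gates mixed classes, 5 comparisons within a class were added after the clusters had been seen. In macrophage-like wells, 291 of 6609 genes were called between mutant and wild-type bMs, 196 higher and 95 lower. Leaving out wild-type bM plate 1 or 2 gave 93 and 97 genes, and leaving out mutant bM plate 1 or 2 gave 239 and 513. DESeq2 called 114, and with each well thinned to 1000 UMIs edgeR called 63 of the 2145 genes then tested. The class rests on clusters 1 and 4. Cluster 1 held 109 and 121 of the wild-type bM wells and 61 and 73 of the mutant bM wells, and cluster 4 held 7 and 9 of the wild-type and 107 and 44 of the mutant wells. With cluster 1 alone, 207 genes were called, of which 122 were among the 291 with the same direction. Of 45 values of named genes, 12 then fell short of the threshold: those of fn1a, fabp7b, egr4, rnd3b, c1qa, junbb, lyz, cybb, abca1a, plin2, ctsk and ctsla. marco, whose sign changed, lost its call as well (adjusted p 0.87).

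The 10 genes named as higher in mutant macrophage-like wells were aqp8b, id4, tcnbb, xkr8.2, pacsin3, nupr1b, fn1a, fabp7b, appb and epdl1. tcnbb rose from 21.14 ± 7.78 to 342 ± 94.7 CPM (log2 fold change 4.03, SE 0.34, adjusted p 3.17e-05), and aqp8b from 0.83 ± 1.18 to 104 ± 45.2 CPM (6.67, SE 0.70, adjusted p 0.000188). fn1a, which encodes fibronectin, rose from 21.6 ± 2.41 to 149 ± 55.1 CPM. The 10 genes named as lower were ccl38a.5, ccl38.6, caspb, hdac8 (ENSDARG00000105159), moxd1, aif1l, egr4, rnd3b, grn2 and egr2a. egr2a fell from 577 ± 26.7 to 140 ± 9.53 CPM (−2.04, SE 0.18, adjusted p 3.17e-05), and caspb from 83.3 ± 4.79 to 10.5 ± 1.72 CPM (−2.94, SE 0.34, adjusted p 0.000296). egr1 (−1.47), dusp2 (−1.25) and junbb (−1.09) of the dissociation and stress list were lower too, and 4 of its 26 members were called lower (5 adjusted over the list alone) against 1 higher. In wild-type macrophage-like wells of the macrophage gate egr2a stood at 651 ± 5.40 CPM, near the wild-type bM level. Whether the genotype or the dissociation of the cells lay behind the lower values in the mutant was not tested.

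Of the macrophage list, 6 of 21 members were called higher and 1 lower in mutant macrophage-like wells (7 and 2 adjusted over the list alone). slc40a1, the iron exporter, was higher by 1.88 (log2; SE 0.19, adjusted p 8.59e-05), with 1491 ± 236 CPM against 406 ± 42.4 CPM. marco was higher by 1.41, c1qa by 1.80, c1qc by 1.55 and the complement gene cfp by 1.19. slc40a1, marco and ctsk are among the genes that set cluster 4 apart, and with cluster 1 alone the log2 fold change of marco was −0.08. lect2l rose by 2.12 and lyz by 0.72. Both are on the neutrophil list, as is mpx, which did not pass. Neutrophil-like wells made up 26.6% of mutant and 16.6% of wild-type bM wells. Whether neutrophil RNA from other wells lay behind the values of lect2l and lyz was not tested for each gene. The lysosomal genes ctsk (1.13) and ctsla (0.73) and the lipid genes abca1a (0.92) and plin2 (1.77) were higher. lygl1 (−1.29), runx3 (−1.94), cybb (−0.77) and cd74a (−2.84) were lower. csf1ra was 131 ± 64.8 CPM in mutant and 55.2 ± 13.8 CPM in wild-type bM macrophage-like wells (log2 fold change 1.23, SE 0.34, adjusted p 0.0592), and csf1rb (0.53, SE 0.41, adjusted p 0.549) did not pass either. mpeg1.1 (0.16) and mpx (0.18) did not pass, and both changed sign under 1 alternative. Among the lists, lipid handling had a median of 0.73 with 4 of 16 members called higher (9 adjusted over the list alone; camera adjusted p 1.71e-05, 0.362 with an estimated correlation). Lysosome had a median of 0.29 with 6 of 38 called higher (7 adjusted over the list alone; adjusted p 0.00435, 0.422 with an estimated correlation).

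**Figure D3:**
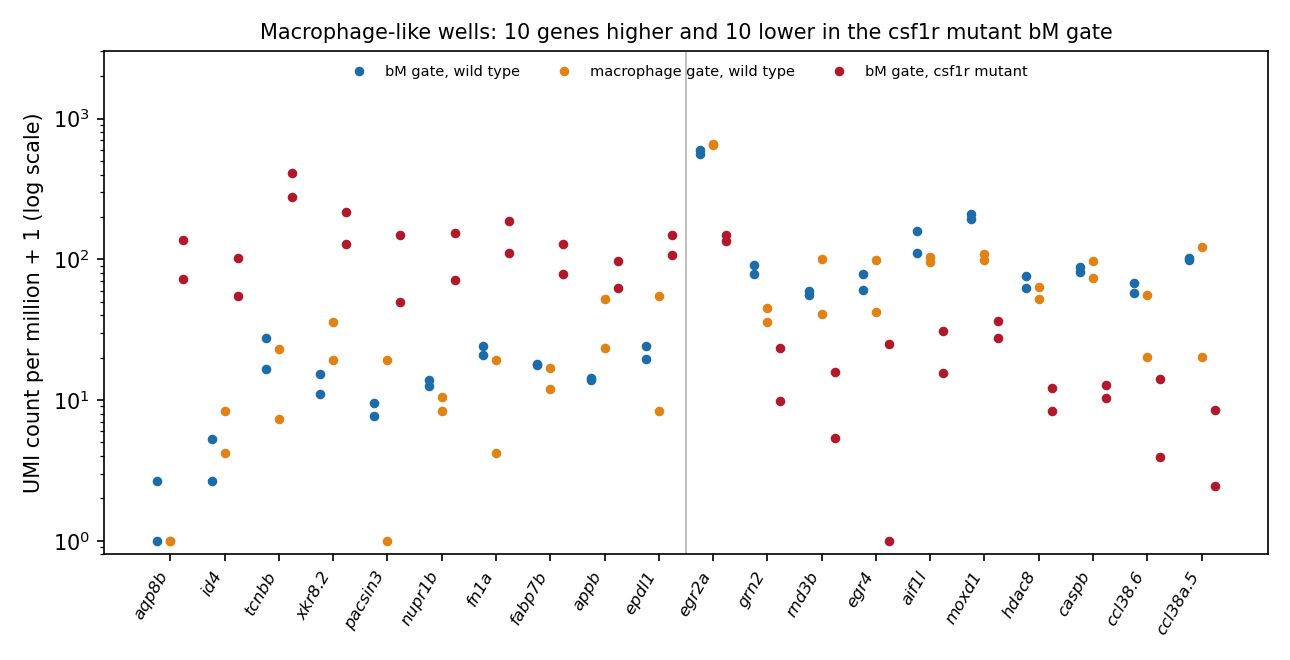
UMI counts in CPM plus 1, on a log axis, of the 10 genes named as higher and the 10 named as lower in macrophage-like wells of the mutant bM gate. Points are single plates of the wild-type bM gate, the wild-type macrophage gate and the mutant bM gate; caspb stands at 10.5 CPM in mutant and 83.3 CPM in wild-type bMs on average.

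In neutrophil-like wells of the same gates, 104 of 4450 genes were called, 65 higher and 39 lower in the mutant, and leaving out 1 plate at a time gave 48 (without wild-type bM plate 1) to 122. DESeq2 called 28, and edgeR after thinning 21 of the 1504 genes then tested. Named as higher were nuggc.2, eppk1, jcada, mogs, foxo1a, icn, OSCP1, rbms2a, zyx and spcs2. Named as lower were ccl38a.5, gstm.2, pdlim2, prune2, tacc3, aif1l, ANPEP (ENSDARG00000036809), serinc5, hist1h4l (ENSDARG00000105409) and vdac1. Of the neutrophil list, 6 of 15 members were higher (10 adjusted over the list alone), lect2l by 0.68, nccrp1 by 0.72 and cpa5 by 0.63 among them. The clusters of the class differed in weight: cluster 2 held 37 and 45 of the 57 and 62 wild-type wells and 74 and 88 of the 85 and 102 mutant wells, and cluster 5 held 15 and 13 against 6 and 8. fli1a reached 194 ± 21.12 CPM in mutant and 193 ± 6.82 CPM in wild-type bM neutrophil-like wells, a log2 fold change of 0.01 whose sign changed with the setting. In blood progenitor-like wells, 4 of 5380 genes were called, all lower. Without the filter on low counts 32 were called, 19 higher and 13 lower, so the direction depended on the setting. The 4 are BX322618.1 (−2.59), CR753876.1 (−2.52), BX901920.1 (−2.29) and BX248082.2 (−1.67), named after their values were seen. All 4 were also called lower in macrophage-like wells. In neutrophil-like wells BX322618.1 was called lower (−1.28) and BX901920.1 higher (1.47), and the other 2 were not called. Leaving out wild-type bM plate 1 or 2 gave 16 and 9 genes there, and leaving out mutant bM plate 1 or 2 gave 93 and 213.

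Between wild-type bMs and wild-type macrophages, which asks how vessel macrophages differ from those in tissue, 2233 of 12008 genes were called, 807 higher and 1426 lower in bMs. Leaving out wells of clusters named for other cell types gave 29, 8 higher and 21 lower, and with only the plates compared 4769. The unnamed cartilage, cell cycle and kidney tubule clusters stayed in when those wells were left out. The count was 532 without bM plate 1, 197 without bM plate 2, 470 without macrophage plate 1 and 620 without macrophage plate 2. fli1a was higher by 2.51 (SE 0.33, adjusted p 0.0028). Within the wild-type bM gate it stood at 361 ± 9.53 CPM in blood progenitor-like wells but at 25.4 ± 12.35 CPM in macrophage-like wells. csf1ra (−1.40, SE 0.76, adjusted p 0.229), csf1rb (0.84), mpeg1.1 (0.46), mpeg1.2 (0.09) and mpx (0.09) did not pass. Without the wells of clusters named for other cell types, the last 4 changed sign. Named as higher were col9a3, drll.1, spi2, tox2, lmo2, cnmd, drl, tal1, qrsl1 and znfl2a, with log2 fold changes of 2.86 to 4.01. spi2, tox2 and qrsl1 lead the blood progenitor-like cluster, drll.1, drl, tal1 and znfl2a an erythroid-like one, and col9a3 and cnmd are cartilage genes. Named as lower, by −6.05 to −7.35, were smyhc2 (ENSDARG00000103969), trpv6, smyhc3, jph2, nptx1l, tyrp1a, myhz1.2, s100a11, ckmt2b and syt11a. These include muscle genes, ionocyte genes (trpv6, s100a11) and pigment genes (tyrp1a, syt11a). The cell cycle list was higher in bMs with a median of 1.90, with 19 of 30 members called (29 adjusted over the list alone). Cluster 10, led by cell cycle genes, held 25 and 38 wells of the bM gate and 3 and 4 of the macrophage gate. Blood progenitor-like wells made up 19.4% and 3.74% of these gates, so the list need not describe macrophages.

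In macrophage-like wells alone, 6 of 6609 genes were called between these gates, 1 higher and 5 lower in bMs. Leaving out 1 plate at a time gave 1 (without macrophage plate 2) to 8, DESeq2 called 22, and edgeR after thinning 1. The 5 lower genes were glula (−3.08), ccl34b.1 (−2.30), apoc1 (−2.27), tnnt2d (−2.12) and nme2b.2 (−1.49). ccl34b.1 stood at 269 ± 3.57 CPM in bMs and 1329 ± 105 CPM in the macrophage gate (SE 0.16, adjusted p 2.51e-05). tnnt2d is a muscle gene, and the muscle list had a median of −0.78, with 0 of 14 members called and 6 adjusted over the list alone (camera adjusted p 1.88e-13, 0.231 with an estimated correlation). tnnt2d leads the muscle-like cluster 20. Muscle-like wells made up 7.87% ± 0.34 of the macrophage gate and 0% of the kept wild-type bM wells. Whether RNA from muscle-like wells lay behind the values of tnnt2d and the muscle list was not tested. fli1a did not pass in these wells, at 25.4 ± 12.3 CPM in bMs and 16.6 ± 8.05 CPM in the macrophage gate (0.60, SE 0.62, adjusted p 0.875).

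Wild-type bMs and wild-type neutrophils, a comparison of the vessel gate with another myeloid cell, differed in 4856 of 12008 genes, 2400 higher and 2456 lower in bMs. Leaving out wells of clusters named for other cell types gave 2604. The count was 2731 without bM plate 1, 2353 without bM plate 2, 2550 without neutrophil plate 1 and 2799 without neutrophil plate 2. mpeg1.1 was higher by 5.37 (SE 0.60, adjusted p 0.000408), csf1rb by 2.90, mpeg1.2 by 2.35 and fli1a by 1.85, and mpx was lower (−0.77, SE 0.22, adjusted p 0.0208). csf1ra did not pass (−1.98, adjusted p 0.0647). Without the wells of clusters named for other cell types, csf1ra and fli1a changed sign. Named as higher were 2 rows called MFAP4 (ENSDARG00000038681 and ENSDARG00000089667), cd83, tnfsf12, drl, acod1, drll.1, blf, spi2 and ms4a17a.8, by 5.39 to 7.34. Named as lower, by −6.15 to −8.34, were pts, smyhc3, smyhc2 (ENSDARG00000103969), jph2, syt11a, mgat4b, myh7bb, ckmt2b, trim63a and bscl2l. Of these, smyhc2, smyhc3 and ckmt2b lead a muscle-like cluster and syt11a a pigment-like one.

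Neutrophil-like wells of the bM gate and of the neutrophil gate differed in 575 of 4450 genes, 250 higher and 325 lower in the bM gate. The count was 385 and 327 without bM plate 1 or 2, and 270 and 289 without neutrophil plate 1 or 2. DESeq2 called 192, and edgeR after thinning 146. The gates came from different transgenic lines, and different clusters held most of the class: cluster 2 in the bM gate (37 and 45 wells) and cluster 9 in the neutrophil gate (93 and 103 wells). The naming rule gave itln1, dnase1l4.1, cdaa, ablim1b, tyms, gstm.2, fkbp5, nusap1, top2a and aif1l as higher in the bM gate. It gave osbp2, cox4i1l, ly97.3, ved, aldh2.2, brinp3a.2, rab11bb, eno1a, ryr3 and mgst1.1 as lower. itln1 stood at 224 ± 78.8 CPM in the bM gate and 1.63 ± 2.31 CPM in the neutrophil gate (6.80, SE 0.67, adjusted p 1.48e-06). Of the cell cycle list, 21 of 26 members were called higher (23 adjusted over the list alone), with a median of 1.88 and cdk1 at 2.49. mpx (0.13) and fli1a (0.17) did not pass. mpeg1.1 was higher by 4.60, at 48.1 ± 1.71 CPM, against 1231 ± 97.7 CPM in macrophage-like wells of the same gate.

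Wild-type macrophages and wild-type neutrophils differed in 493 of 12008 genes, 354 higher and 139 lower in macrophages. The balance was near even with only the plates compared (1206 higher, 1201 lower) and without the wells of clusters named for other cell types (671 higher, 634 lower). The count was 130 and 115 without macrophage plate 1 or 2, and 80 and 49 without neutrophil plate 1 or 2. mpeg1.1 was higher by 4.91 (SE 0.60, adjusted p 0.00375) and mpeg1.2 by 2.26. csf1ra (−0.58), csf1rb (2.06, adjusted p 0.0542), fli1a (−0.66) and mpx (−0.86, adjusted p 0.0644) did not pass, and csf1ra changed sign under 2 alternatives. Named as higher were ccl34b.1, the same 2 MFAP4 rows, cd83, acod1, s100a11, trpv6, dct, pvalb8 and lgals3bpb, by 4.97 to 6.73. ccl34b.1, acod1 and lgals3bpb lead the macrophage-like cluster 1. trpv6 and s100a11 lead the ionocyte-like cluster 22, which held 9 and 8 macrophage but 0 and 1 neutrophil wells. dct leads the pigment-like cluster 18, which held 6 and 8 macrophage but 0 and 0 neutrophil wells. Named as lower were ly97.3, osbp2, rbp4l, cd151, fn1b, ved, alpl, tspan2a, s1pr4 and cpa5. ly97.3 had no count in either macrophage plate and was at least 60.4-fold lower, taking a floor of 3 counts per plate. The macrophage list was higher with a median of 3.26 and 15 of 21 members called (18 adjusted over the list alone).

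Metaphocytes of the mutant and wild-type macrophages share a sort, GFP without Cherry, and comparing them asks what it holds in each genotype. The fit called 847 of 12008 genes, 276 higher and 571 lower in metaphocytes. Without the wells of clusters named for other cell types the balance turned, with 382 higher and 216 lower. With only the plates compared edgeR called 0, with 1601 at an unadjusted p under 0.05, and DESeq2 called 1027 on all plates. The count was 3343 without metaphocyte plate 1 and 1411 without plate 2. It was 195 without macrophage plate 1 and 19 without macrophage plate 2. mpeg1.1 was lower (−3.06, SE 0.53, adjusted p 0.0148), as were fli1a (−1.95) and mpx (−1.25), and mpx changed sign without the wells of clusters named for other cell types. csf1ra (2.102, adjusted p 0.122), csf1rb (−1.71, adjusted p 0.0661) and mpeg1.2 (−1.64, adjusted p 0.0566) did not pass, and csf1ra was −0.01 without metaphocyte plate 2. Named as higher were s100b, nhsl1a, gata2a, fabp2, ppp3ca, alpl, lim2.2, dixdc1b, gldc and sox4a (ENSDARG00000004588), by 2.89 to 6.87. gata2a and lim2.2 lead the pigment-like cluster 6, and gata2a, fabp2 and ppp3ca lead cluster 19. Named as lower, by −3.39 to −6.37, were trpv6, s100a11, atp1a1a.2, atp1b1b, plaua, pvalb8, fthl29, ccl34b.1, fthl28 and mafbb. trpv6 and s100a11 lead the ionocyte-like cluster 22, which held 9 and 8 macrophage wells and 2 and 0 metaphocyte wells, and atp1b1b is on the ionocyte list. The macrophage list was lower with a median of −1.93 and 12 of 21 members called (18 adjusted over the list alone). The metaphocyte list was lower with a median of −1.77 and 5 of 11 members called (8 adjusted over the list alone). Its member cldne also leads cluster 22, and ionocyte-like wells were 3.35% of the macrophage gate and 0.39% of the metaphocyte gate. No cluster was named metaphocyte, so the list compares mixed gates and not metaphocytes with macrophages. The 2 metaphocyte plates differed in their clusters: cluster 19 held 2 wells of plate 1 and 213 of plate 2, and clusters 20 and 23 held 35 wells each of plate 1 and 1 and 0 of plate 2. The chi-square per gene between plates was 39.08 for metaphocytes and 2.71 to 8.28 in the other groups. Since the fit shares its spread per gene over all groups, counts of called genes are not comparable between comparisons.

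Mutant bMs and mutant metaphocytes, the Cherry-positive and Cherry-negative cells of the mutant, differed in 4264 of 12008 genes, 2053 higher and 2211 lower in bMs. The count fell to 754 without wells of clusters named for other cell types, 226 higher and 528 lower, and with only the plates compared 1701. Leaving out 1 plate at a time gave 2402 (without bM plate 2) to 5236 (without metaphocyte plate 1). All 6 genes named first passed. fli1a was higher by 4.29 (SE 0.38, adjusted p 0.000252), mpeg1.1 by 3.79, csf1rb by 2.52, mpx by 2.21 and mpeg1.2 by 2.06, and csf1ra was lower (−2.49, adjusted p 0.0314). csf1ra rested on metaphocyte plate 2, without which its log2 fold change was −0.38 and not called, and it was not called without mutant bM plate 1 or 2 either. Leaving out wells of clusters named for other cell types ended the calls of csf1ra, csf1rb, mpeg1.2 and mpx. Named as higher besides fli1a were atp1a1a.3, spi2, marco, iqgap2, grn1, slc16a9a, blf, myb and c1qb, by 4.11 to 5.11. Named as lower were mlphb, pts, arhgef33, apoda.1, s100b, pnp4a, akap12a, syngr1a, pax7b and alx4b. mlphb had no count in either mutant bM plate and was at least 36.6-fold lower, taking a floor of 3 counts per plate, and the others were lower by −6.85 to −7.81. The neural crest and pigment list was lower with a median of −4.91 and 9 of 11 members called (11 adjusted over the list alone).

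The interaction asks whether the difference between the Cherry-positive and Cherry-negative mpeg gates is itself different in the mutant. Its value is the log2 fold change of Cherry-positive over Cherry-negative cells in the mutant minus that in wild type. It called 297 of 12008 genes, 272 with a positive and 25 with a negative value. It called 0 without wild-type bM plate 1 or 2, macrophage plate 1 or 2, or mutant bM plate 1, with 1337, 1464, 1581, 1462 and 1592 genes at an unadjusted p under 0.05. It called 238 without mutant bM plate 2, 1862 without metaphocyte plate 1 and 749 without metaphocyte plate 2, and DESeq2 called 432 on all plates. Without the wells of clusters named for other cell types, 87 genes were called, 13 positive and 74 negative, and with only the 8 plates compared 1 gene was called. Of the genes named first, mpeg1.1 (3.33, SE 0.71, adjusted p 0.0463) and mpx (2.12, SE 0.31, adjusted p 0.0201) passed. csf1ra (−1.09), csf1rb (1.68), fli1a (1.77) and mpeg1.2 (1.96) did not, with adjusted p of 0.705, 0.222, 0.109 and 0.125, and csf1ra changed sign without metaphocyte plate 2. Macrophage-like and neutrophil-like shares also differed more between the gates in the mutant than in wild type. The values of mpeg1.1 and mpx therefore need not mean a change within a class. Named with a positive value were atp1b1b (7.84), trpv6 (7.22), atp1a1a.3 (6.999), cldne (6.27) and atp1a1a.2 (6.27). Ionocyte-like wells made up 3.35% ± 0.37 of the wild-type macrophage gate. None was found in the 360 and 357 wells of the wild-type bM plates. Taking a floor of 3 wells per plate, shares of up to 0.833% and 0.84% stay possible. trpv6 was lower in wild-type bMs than in macrophages (−7.25), a difference that its interaction offsets. Named with a negative value were s100b (−7.28), gata2a (−4.76), col9a3 (−3.76), sox4a (ENSDARG00000004588; −2.84) and sort1a (−2.76). s100b was lower in mutant bMs than in metaphocytes (−7.28).

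Some named genes have rows of the same or a similar name in the files, between which the counting could split reads if their sequences are alike. They include mpeg1.1 and mpeg1.2, ccl38a.5 and ccl38.6, the MFAP4 rows, the smyhc and atp1a1a rows, and mmp13a. Their sequences were not compared, so their single values may be uncertain. No value of any gene or spike-in exceeded 135 in a well, and the 4 most abundant spike-ins averaged 74.3 to 87.3 per well and plate.

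**Figure D4:**
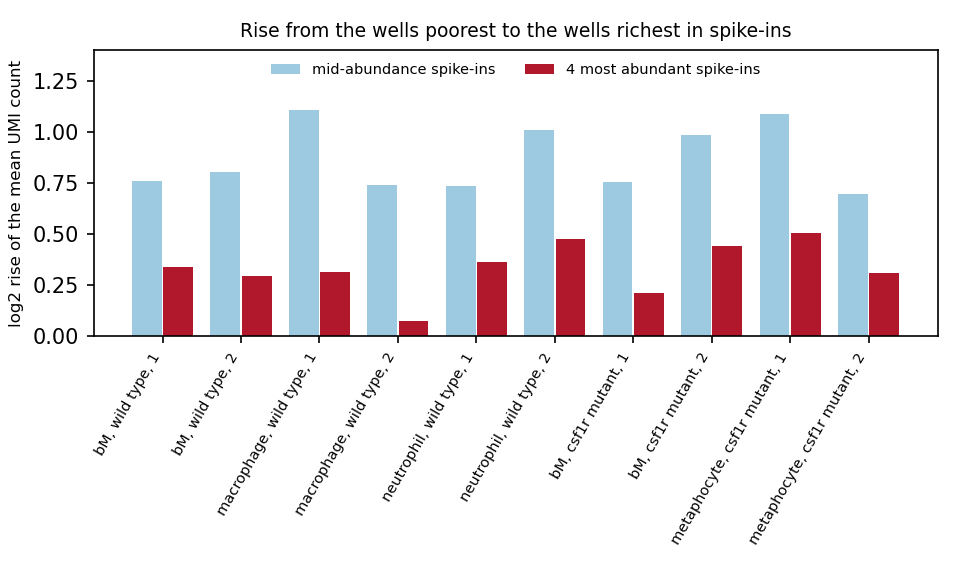
Log2 rise of the mean UMI count from the 25% of wells poorest in spike-ins to the richest 25%, per plate. Bars show mid-abundance spike-ins and the 4 most abundant spike-ins, whose rise was 9.7% to 49.1% of the former.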

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

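The interaction was chosen before the data were examined, and no test in this part was chosen after the result was seen. It asked whether the difference between the Cherry-positive and Cherry-negative mpeg gates differs between mutant and wild type, and a test of that difference itself (edgeR's interaction contrast) brought these results here.

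It called 297 genes, and 100 with plate number as a block. The number called depended strongly on single plates, as given above. Among the genes named in every comparison, mpeg1.1 had an interaction log2 fold change of 3.33 and mpx of 2.12. The value is the gate difference in the mutant minus that in wild type. Named genes with a positive value were atp1b1b (7.84), trpv6 (7.22), atp1a1a.3 (6.999), cldne (6.27) and atp1a1a.2 (6.27). Those with a negative value were s100b (−7.28), gata2a (−4.76), col9a3 (−3.76), sox4a (ENSDARG00000004588; −2.84) and sort1a (−2.76).

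The wells behind these gates differ in class. Macrophage-like wells made up 41.1% of mutant bMs and 3.14% of metaphocytes, but 34.3% of wild-type bMs and 23.8% of macrophages. Neutrophil-like wells made up 26.6% and 5.06% in the mutant, and 16.6% and 13.6% in wild type. Both shares thus differed more between the gates in the mutant, as mpeg1.1 and mpx did. The values of mpeg1.1 and mpx therefore need not mean a change of expression within a class. Without the wells of clusters named for other cell types, 87 genes were called, 26 of them among the 297 and in the same direction, and 14.9% of the 87 were positive against 91.6% of the 297. Wells of the unnamed clusters stayed in. With only the 8 plates compared, 1 gene was called. Whether the remaining difference belongs to the genotype was not tested, and no biological explanation was tested.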

How the results depend on the processing

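Tests within a class, whole UMI numbers, values set to at most 20, the larger macrophage-like cluster alone and the mpeg1.1 minimum were chosen after the data were seen. Of 3412 gene values under an alternative, 2851 kept direction and side of the threshold, 497 fell short of it, 41 newly passed and 23 reversed. Whole UMI numbers left all 159 gene values on their side. For the changes below the cause was not tested, except that fewer wells, plates or UMIs entered where the alternative removes them.

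Over all wells, counts of called genes that moved beyond 1.5 times were as follows. For mutant against wild-type bMs (25), DESeq2's Wald test gave 121, no filter 620, the plate block 2, only the plates compared 104, at least 3000 UMIs 6, thinning 45, leaving out other-type wells 191 and values set to at most 20 gave 14. For bMs against macrophages (2233), only the plates compared gave 4769, thinning 787 and leaving out other-type wells 29. For metaphocytes against macrophages (847), no filter gave 1805 and only the plates compared 0 in edgeR, with 1601 at an unadjusted p under 0.05 and 1027 by DESeq2 on all plates. For bMs against neutrophils (4856), thinning gave 2186 and leaving out other-type wells 2604. For macrophages against neutrophils (493), no filter gave 1416, only the plates compared 2407 and leaving out other-type wells 1305. For mutant bMs against metaphocytes (4264), only the plates compared gave 1701, thinning 2478 and leaving out other-type wells 754. For the interaction (297), no filter gave 1039, the plate block 100, only the plates compared 1 and leaving out other-type wells 87.

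In macrophage-like wells, bMs against macrophages (6) gave 22 with DESeq2, 75 without the filter, 21 with the block, 35 with only the plates compared, 1 with thinning and 23 with the mpeg1.1 minimum. Mutant against wild-type bMs (291) gave 114 with DESeq2, 517 without the filter and 63 with thinning. In neutrophil-like wells, mutant against wild type (104) gave 28 with DESeq2 and 21 with thinning, and bMs against neutrophils (575) gave 192 and 146. In blood progenitor-like wells (4), no filter gave 32 and the block 68.

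Leaving out 1 plate at a time, a lone plate being assumed to vary like the other groups, gave these ranges: 197 to 620 for bMs against macrophages, 0 to 15 for mutant against wild-type bMs, 19 to 3343 for metaphocytes against macrophages, 2353 to 2799 for bMs against neutrophils, 49 to 130 for macrophages against neutrophils, 2402 to 5236 for mutant bMs against metaphocytes and 0 to 1862 for the interaction. The comparisons within a class gave 1 to 8 and 93 to 513 (macrophage-like), 48 to 122 and 270 to 385 (neutrophil-like) and 9 to 213 (blood progenitor-like).

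Camera with an estimated correlation passed 0 lists in all 12 comparisons. Fry passed 2 lists for mutant against wild-type bMs (15 with camera), 16 for bMs against neutrophils (10), 13 for the interaction (20) and 8 for macrophages against neutrophils (16). Within classes it passed 1 and 0 (macrophage-like), 1 and 2 (neutrophil-like) and 0 (blood progenitor-like).

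Reversed log2 fold changes: thinning gave csf1rb 0.046 in mutant against wild-type bMs, csf1ra 0.072 in macrophages against neutrophils and fli1a −0.093 in neutrophil-like wells of the mutant. Leaving out other-type wells gave csf1rb −0.34, mpeg1.1 −0.23, mpeg1.2 −0.41 and mpx −0.46 in bMs against macrophages. It gave csf1rb 0.088, fli1a 0.22 and mpeg1.1 −0.007 in mutant against wild-type bMs, mpx 0.14 in metaphocytes against macrophages, csf1ra 0.29 and fli1a −0.37 in bMs against neutrophils, and csf1ra 0.85 in macrophages against neutrophils. The larger macrophage-like cluster alone gave mpeg1.1 −0.13 and marco −0.082. Over the plates left out, csf1ra ran from −1.90 to 1.01 in the interaction and from −0.006 to 2.89 in metaphocytes against macrophages, mpeg1.1 from −0.42 to 0.68 in mutant against wild-type bMs and mpeg1.2 from −0.18 to 0.54 in bMs against macrophages. Within classes, mpx ran from −0.084 to 0.38 in macrophage-like and fli1a from −0.085 to 0.13 in neutrophil-like wells of the mutant.

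Of 100 class shares under an alternative, 43 moved by more than 1 SD, by 15.76 percentage points at most. At resolution 0.5 no cluster was named erythroid, and blood progenitor-like shares were 35.14% (wild-type bMs), 21.46% (mutant bMs), 5.7% (macrophages), 0.99% (metaphocytes) and 0.64% (neutrophils). Macrophage-like shares were 45.48%, 28.16%, 4.42% and 2.05% in wild-type bMs, macrophages, metaphocytes and neutrophils, pigment-like shares 0% and 34.09% in wild-type bMs and macrophages, and unnamed shares 2.79% and 4.35% in wild-type and mutant bMs. At resolution 2, blood progenitor-like shares were 1.18%, 0% and 0.32% in macrophages, metaphocytes and neutrophils, and erythroid-like shares 4.52% and 3.28% in macrophages and neutrophils. Macrophage-like shares were 40.74% and 26.98% in wild-type bMs and macrophages, pigment-like shares 0.14%, 32.72% and 42.49% in wild-type bMs, macrophages and neutrophils, and the unnamed share of wild-type bMs 9.48%. With at least 3000 UMIs, blood progenitor-like shares were 23.98%, 4.3%, 0.49% and 0.63% in wild-type bMs, macrophages, metaphocytes and neutrophils, the erythroid-like share of macrophages 1.44%, and macrophage-like shares 43.76%, 31.37% and 3.8% in wild-type bMs, macrophages and metaphocytes. Muscle-like shares were 9.06% and 8.04% in macrophages and neutrophils, pigment-like shares 0%, 30.48% and 54.72% in wild-type bMs, macrophages and neutrophils, neutrophil-like shares 4.22% and 24.14% in metaphocytes and neutrophils, and unnamed shares 2.27%, 4.01%, 3.06% and 9.08% in wild-type bMs, mutant bMs, macrophages and neutrophils.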

Other observations

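The test on doublets of a pigment cell and a neutrophil and the test on genes called in both classes were chosen after the result was seen.

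In macrophage-like wells, 291 genes differed between mutant and wild-type bMs. RNA of neutrophils from other wells would bring genes that neutrophils hold in excess. Of the 196 genes higher in the mutant, 9.2% were more abundant in neutrophil-like than in macrophage-like wells of both mutant plates. Over all genes tested the share was 29.4%. The 196 were chosen for high values in these same macrophage-like wells, which can lower their share, so 29.4% is no fair baseline. That most of the 196 were not in excess in neutrophil-like wells of both plates argues against this source for most of the set. It stays open for the 18 genes that were. RNA of other cell types was not tested. Variants carried along with the mutations would gather near csf1ra and csf1rb. The up to 50 tested genes on either side of each held 3.35% of the 239 called genes with a known position and 2.32% of the genes tested (Fisher's exact test, 2-sided, p 0.27), which argues against them for the set. The regions differed: 6 of 69 genes were called around csf1ra, out of 10 of 262 on its chromosome, and 2 of 71 around csf1rb. Carried variants therefore stay open for genes in those regions, such as cd74a near csf1ra and vdac1 near csf1rb, as do variants elsewhere in the genome. A difference that all classes share would move the same genes alike in neutrophil-like wells. Over 157 genes tested in both, the median signed change there was 0.211 (quartiles −0.085 to 0.721) against 1.187 in macrophage-like wells, or 17.7%, which argues against a shared difference as the cause of the whole change of the set. Still, 106 of the 157 moved the same way there. In blood progenitor-like wells 127 of 165 did (quartiles 0.04 to 0.721), and the measure was 29.8%, above the 25% set as the lower bound. A shared difference that makes up part of these changes stays open, and not for the genes called in both classes alone. All 4 genes called in blood progenitor-like wells were also called lower in macrophage-like wells. Of these, BX901920.1 was called higher in neutrophil-like wells (1.47), which argues against a difference shared by all 3 classes for that gene, and only BX322618.1 was called lower in all 3.

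A further test covered a part of the set. In both macrophage-like and neutrophil-like wells, 21 genes were called the same way. Of the 20 tested in blood progenitor-like wells, 18 moved the same way there, with a median signed change of 0.688 against 1.737, or 39.6%. For these genes, a difference shared by all classes and one of the myeloid classes cannot be told apart, because that value lies between the 25% and 50% set as bounds. The loss of Csf1r may lie behind changes in this set, but genotype, line and plates go together in this design, so that explanation was not tested further. Cluster 4, which held 107 and 44 mutant but 7 and 9 wild-type bM wells, may also stand for a different subset of macrophages: with cluster 1 alone 207 genes were called, 122 of them among the 291.

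Pigment-like wells made up 45.5% of the neutrophil gate, which was sorted for GFP driven by mpx. A pigment cell sorted together with a neutrophil would bring neutrophil transcripts. mpx in pigment-like wells reached 2.66% and 2.62% of its level in neutrophil-like wells of plates 1 and 2, which argues against such doublets. GFP in these wells reached 1.28% and 1.15% of the level in neutrophil-like wells, so that the ratio of GFP to mpx was 0.48 and 0.44 times that in neutrophil-like wells. GFP expressed by the pigment-like cells in excess of carried-over RNA, which would give a ratio above 2, was not seen. The ratio also lies below the 0.67 to 1.5 set for GFP transcripts from neutrophils in other wells, so whether these account for the GFP transcripts found stays open. Light scattered or emitted by pigment in the sorter was not tested, nor was a biological explanation.

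No gene had a value far above those of the most abundant spike-ins. If the number of UMIs counted per gene and well has a ceiling, abundant spike-ins should rise less than others from wells poor in spike-ins to wells rich in them. The 4 most abundant rose by 9.7% to 49.1% of the rise of mid-abundance spike-ins, on the log scale, over the 10 plates, in line with a ceiling. Fold changes of the most abundant genes may then be too small. With values above 20 per gene and well set to 20, 14 genes were called between mutant and wild-type bMs in place of 25.

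The 2 metaphocyte plates differed from each other more than the plates of any other group. The chi-square per gene between the 2 plates was 39.08, against 2.71 to 8.28 in the other groups.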
